A study of Mus musculus with 6 samples.

How the data were processed

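T-bet binding was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse induced regulatory T cells (iTreg cells). Per the labels' protocols, naive CD4 T cells of Balb/c mice were sorted, activated with plate-bound anti-CD3 and anti-CD28 (10 µg/ml each) and kept for 7 days in medium with 33 ng/ml TGF-β1, which drives the regulatory fate, together with IL-2 at 20 ng/ml. Chromatin was crosslinked with formaldehyde for 20 minutes and precipitated with a rabbit serum raised against T-bet. Libraries of 150 to 350 bp were sequenced from one end with reads of 35 or 50 bp; the labels do not say which library had which read length. The 6 samples comprised 2 wild-type (WT) ChIP libraries, 1 ChIP library from T-bet knockout (KO) cells, and 3 input libraries. Samples were grouped by their titles.

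One peak list was deposited for each of the 3 ChIP libraries. The submitters' processing notes name CASAVA, Bowtie2, MACS 1.4 and the mouse build mm9. The settings of the tools, the read filters and the control used for each peak call are not given in the sources used here. Each list belonged to a single library, so peaks had not been called on pooled replicates. The lists hold 5 columns without a header: chromosome, start, end, a MACS peak name and a score. The score deposited by the authors is the peak caller's value for each peak. Its scale is not stated. No score was below 70.10. On the scale of −10 log10(p), that lowest score would equal a p of 9.8e-08. Scores were used to rank, filter or split the peaks within a list. Their log10 values were also correlated between the WT lists across shared sites, which compares the lists' scores without a common scale. Read counts and sequencing depth are unknown, the input libraries were not analysed here, and peak heights could not be compared between libraries. Positions are given in mm9, counted from 1.

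Peaks were compared by overlap, with at least 1 bp in common counted as shared. No list held peaks that overlapped one another, and every peak lay within the mm9 chromosome lengths, which were taken from GenomeInfoDb 1.38.1 (R 4.3.3). Chance overlap was estimated from 10000 random placements. In each, all peaks of a chromosome were shifted around it by one random offset, and the test was one-sided for more overlap than chance; the smallest p this allows is 1.0e-04. Scores of peaks with and without a counterpart were compared by a two-sided permutation test of the difference in medians with 100000 resamples, for which the smallest possible p is 1.0e-05. Shares carry exact (Clopper-Pearson) 95% binomial intervals, and densities carry exact 95% Poisson intervals. Both cover counting error over peaks only. Peaks are not independent replicates. The WT libraries are labelled as replicates, but the labels do not say whether they came from separate mice or cultures, so their agreement may measure technical spread alone. With 1 KO library, no test of WT against KO across samples could be made. The deposited names of the replicate 2 and KO lists begin with the same number and that of replicate 1 with another. The sources do not say what it marks. If it marks a batch, one batch holds replicate 1 alone and the other 1 library of each genotype, so the WT replicates cannot be compared within a batch; replicate 2 and KO are the only pair that can. The scripts used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

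The placement test was checked on simulated data. Of 100 sets of 851 peaks placed at random against the WT replicate 1 list, 3% gave a p below the threshold of 0.05, and all 200 of 200 planted overlaps were found. The check used fewer placements than the main tests. Simulated peaks were placed independently of one another, so the rate for clustered peaks was not checked. The planted overlaps show only that overlaps are counted.

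The main WT set was defined as WT replicate 1 peaks that met a WT replicate 2 peak and no KO peak. The peaks to be named were fixed by rule before the data were examined: the 10 peaks of this set with the highest replicate 1 score and the 10 with the highest replicate 2 score, the 5 highest KO peaks, the 5 highest KO peaks without a WT peak, and the 5 highest replicate 2 peaks without a replicate 1 peak. Other named peaks were chosen after their values were seen. The overlap tests and the 2 score tests of replicate 1 peaks were also fixed then. The 3 score tests of replicate 2 and KO peaks, the correlation of scores, the tests of the X share and those of the closing section were not in that plan. The alternatives fixed then were a score of at least 100, a reciprocal overlap of at least 50%, midpoints within 250 bp, merging of peaks within 500 bp, restriction to the 19 autosomes and X, target lists cut to the length of the query list, moving each peak by its own random offset of 10 kb to 1 Mb, extension of KO peaks by 1 kb, no KO filter, a difference in mean rank in place of medians, and leaving out each WT replicate. Joining peaks within 50 kb was added after seeing the data. Planned analyses of gene location, of fixed gene lists and of the T-box motif needed an mm9 annotation and genome. The gene table at hand was of another assembly, GRCm38, so these analyses were not run, peaks were not assigned to genes, and Tbx21, the gene that encodes T-bet, was not inspected in the KO library.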

Results

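T-bet is a T-box transcription factor best known for directing T helper 1 differentiation. The series asked where it binds in regulatory T cells. ChIP-seq peak lists were available for 2 WT iTreg libraries and for 1 library from T-bet KO iTreg cells precipitated with the same serum, which serves as the background of the antibody. The WT replicate 1 list held 7996 peaks, the WT replicate 2 list 851 and the KO list 78. The WT lists were therefore 103-fold and 10.9-fold longer than the KO list, and they differed 9.40-fold from each other. The peaks covered 1.70 Mb in replicate 1, 0.320 Mb in replicate 2 and 0.0428 Mb in the KO library. Median peak width was 175 bp in replicate 1, 353 bp in replicate 2 and 257 bp in the KO library. Median scores were 107.66, 107.85 and 104.00 in the same order. The lengths of the lists depend on sequencing depth and may depend on read length and peak-calling settings. None of these is known per library. The numbers of peaks therefore describe these 3 libraries and do not measure a difference between genotypes.

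The first comparison asked whether the WT replicates held peaks at the same sites. Most of the shorter list was found again in the longer one: 727 of the 851 replicate 2 peaks, or 85.4% (95% interval 82.9 to 87.7%), overlapped a replicate 1 peak. Random placement gave a mean of 1.58 overlapping peaks and at most 9 (one-sided permutation p = 1.0e-04, the smallest the test can give). The KO list passed the same test against the WT peaks, with 56 of 78 peaks met against a chance mean of 0.190. Passing it therefore does not show that the shared sites are bound by T-bet. In the other direction, 760 of the 7996 replicate 1 peaks, or 9.50% (8.87 to 10.2%), met a replicate 2 peak. When replicate 1 was cut to its 851 highest-scoring peaks, 394 replicate 2 peaks, or 46.3%, still had a counterpart.

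Replicate 1 peaks that recurred in replicate 2 had higher scores than those that did not. Their median score was 261, against 103 for the remaining 7236 peaks, a difference of 158 (two-sided permutation p = 1.0e-05, the smallest the test can give; p = 2.5e-05 after Benjamini-Hochberg adjustment over the 5 score comparisons made). By decile of the replicate 1 score, the share met by replicate 2 was 1.88% (1.05 to 3.07%) in the lowest, 8.26% in the eighth, 16.6% in the ninth and 47.1% (43.5 to 50.6%) in the highest. Replicate 2 peaks with a counterpart in replicate 1 had a median score of 113, against 89.2 for the 124 without one (two-sided permutation p = 2.7e-04).

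**Figure D1:**
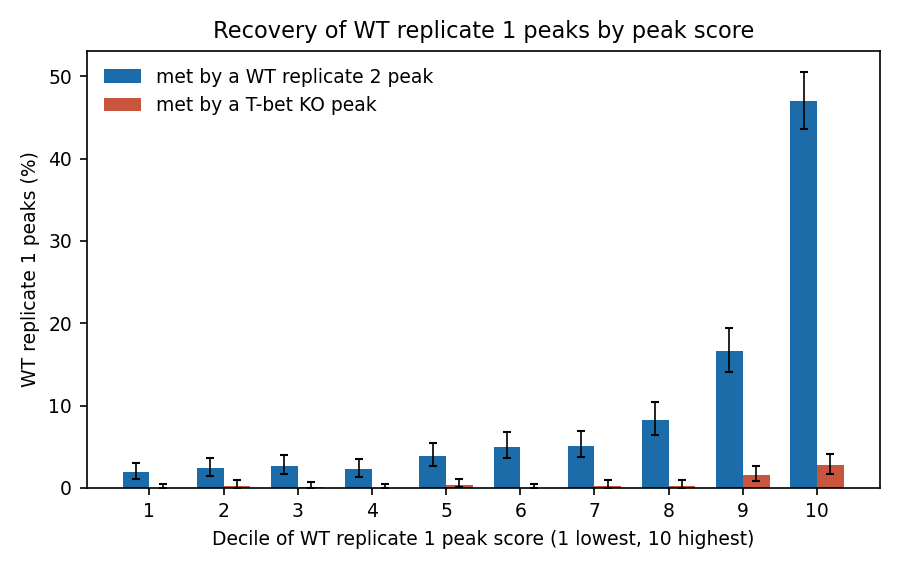
Percentage of WT replicate 1 peaks that overlapped a WT replicate 2 peak (blue) or a T-bet KO peak (red), by decile of the replicate 1 peak score, with exact 95% binomial intervals as error bars. The share met by replicate 2 was 1.88% in the lowest decile and 47.1% in the highest, and the share met by the KO library reached 2.75% in the highest. The lists met held 851 and 78 peaks, which caps the KO share far lower.

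The second comparison set the WT sites against the KO library. A KO counterpart was found for 44 replicate 1 peaks, or 0.550% (0.400 to 0.738%), and 46 replicate 2 peaks, or 5.41% (3.98 to 7.14%). The KO list held only 78 peaks, so these shares were bound to be low. They do not show that WT sites are free of KO signal. Most of the KO peaks, in turn, were also present in WT cells. Of the 78 KO peaks, 56, or 71.8% (60.5 to 81.4%), met a WT peak, against a chance mean of 0.190 and a chance maximum of 4 peaks (one-sided permutation p = 1.0e-04). Both WT replicates held 32 of them, replicate 1 alone 10, replicate 2 alone 14, and 22 KO peaks met neither. The replicate 2 and KO lists carry the same number in their deposited names and replicate 1 another. If it marks a batch, the batch cannot be told apart from the differences of replicate 1 from replicate 2 and from the KO library. Replicate 2 and the KO library would share it, and replicate 2 met 46 of the KO peaks, or 59.0%. Against the 78 highest peaks of each WT list, 12 KO peaks, or 15.4%, had a counterpart (permutation p = 1.0e-04). KO peaks found in WT cells had a median score of 113, against 76.9 for the 22 others (two-sided permutation p = 0.00925, which is also the largest adjusted p of the 5 score comparisons).

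The KO counterparts lay among the stronger WT peaks. Replicate 1 peaks met by a KO peak had a median score of 263, against 107 for the rest (two-sided permutation p = 1.0e-05). For replicate 2 the medians were 142 and 107 (two-sided permutation p = 8.7e-04). The 5 highest KO peaks all had a WT counterpart. The highest, on chromosome 3 from 37018254 to 37019438, had a KO score of 1138; the overlapping replicate 2 peak scored 2056, the highest value of that list, and replicate 1 had no peak there. The next KO peak, on chromosome 17 from 4626159 to 4626615, scored 793 in the KO library, 2675 in replicate 1 and 766 in replicate 2. The peak on chromosome 6 from 129215850 to 129217029 scored 557 in the KO library, 786 in replicate 2 and 79.9 in replicate 1. On chromosome 11, the peak from 86395197 to 86396914 scored 467 in the KO library, 682 in replicate 2 and 107 in replicate 1. On chromosome 6, the peak from 132413673 to 132413850 scored 375 in the KO library, 469 in replicate 1 and 308 in replicate 2.

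The KO peaks without a WT counterpart were weaker. The highest were on chromosome 7 from 107650002 to 107650500, with a score of 208, and on chromosome 2 from 147012259 to 147012466, with a score of 207. Those on chromosome 8 from 19954358 to 19957135, on X from 121328995 to 121329196 and on chromosome 11 from 86394688 to 86395184 scored 125, 118 and 106.

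Sites present in both WT libraries and absent from the KO list numbered 726 by replicate 1 peaks, with a median replicate 1 score of 260 and a median width of 315 bp. Removing the KO counterparts took out 34 of 760 peaks. The site with the highest replicate 1 score lay on chromosome 15 from 59973053 to 59973778, with scores of 1786 in replicate 1 and 591 in replicate 2. It was followed by sites on chromosome 18 from 68349488 to 68350026 (replicate 1 score 1662, replicate 2 score 346), on chromosome 16 from 91533214 to 91534106 (1570 and 362), on chromosome 17 from 8069068 to 8069512 (1312 and 513) and on chromosome 10 from 117355536 to 117355992 (1286 and 615). The remaining sites among the 10 highest had replicate 1 scores of 852 to 1121. They lay on chromosome 11 from 54836514 to 54837048, on chromosome 7 from 88324323 to 88324836, on chromosome 6 from 52912194 to 52912764, on chromosome 10 from 19438412 to 19438908 and on chromosome 19 from 10837855 to 10838599.

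Ranked by the replicate 2 score, the site on chromosome 10 from 117355536 came first and the site on chromosome 15 from 59973053 second. Of the 10 highest by each score, 4 were the same. The others by replicate 2 score included chromosome 17 from 52301891 to 52302276, with a replicate 2 score of 525 and a replicate 1 score of 428, and chromosome 9 from 32818854 to 32819224, with scores of 464 and 403. On chromosome 4, a replicate 2 peak with a score of 451 spanned 2 separate replicate 1 peaks, from 133398853 to 133398976 (score 73.6) and from 133399103 to 133399519 (score 338). Sites on chromosome 17 from 44745842 to 44746184 and on chromosome 15 from 50498961 to 50499352 had replicate 2 scores of 437 and 404. Across the 726 sites, which are not independent replicates, the log10 scores of the replicates correlated with Pearson's r = 0.39 and Spearman's rho = 0.37 (permutation p = 1.0e-05 for each). Pearson's r was 0.37 without the 2 sites farthest from the median replicate 1 score. Some replicate 2 peaks met more than 1 replicate 1 peak, so their scores entered more than once, which the permutation p ignores.

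**Figure D2:**
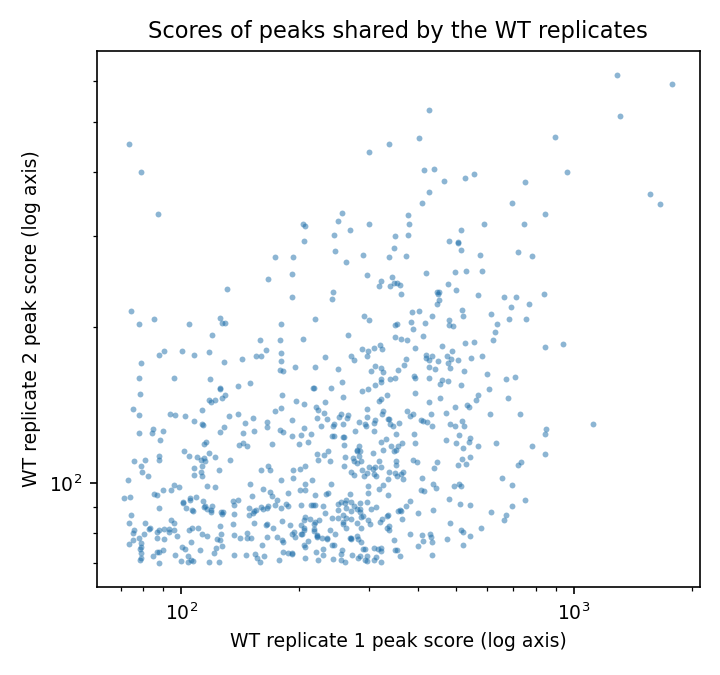
Peak scores of the 726 sites present in both WT libraries and absent from the KO list, with the replicate 1 score on the x axis and the score of the highest overlapping replicate 2 peak on the y axis, both on log axes. Each point is a replicate 1 peak, and points that met the same replicate 2 peak share its score. The scores of the libraries correlated across points (Spearman's rho = 0.37).

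The strongest replicate 2 peaks without a replicate 1 counterpart were, in part, also KO peaks. After the chromosome 3 peak described above came a peak on chromosome 11 from 86623750 to 86625107, with a replicate 2 score of 893 and no peak in either other list. The next, on chromosome 11 from 87571612 to 87572705, scored 245 in replicate 2 and 299 in the KO library. Peaks on chromosome 17 from 35335527 to 35336206 and on chromosome 16 from 84717218 to 84717857 scored 226 and 205 in replicate 2 and 140 and 99.8 in the KO library.

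Peak density was compared between chromosomes. Both WT libraries were densest on chromosome 11, with 5.10 peaks per Mb in replicate 1 and 0.509 in replicate 2, and sparse on X. Replicate 1 had 3.19 peaks per Mb over the autosomes and 0.582 (95% interval 0.472 to 0.710) on X, a ratio of 0.182. Replicate 2 had 0.338 and 0.0900 (0.0504 to 0.149), a ratio of 0.266, which was 0.1585 on 5 X peaks with scores of at least 100. The 726 shared sites included 6 on X, a ratio of 0.124. Chromosome 11 was not the densest for these sites: it held 0.353 per Mb, against 0.431, 0.424 and 0.399 on chromosomes 10, 19 and 17. The KO library had 0.0299 peaks per Mb over the autosomes and 0.0240 (0.0065 to 0.0615) on X, a ratio of 0.802. Its X peaks numbered 4, so the interval spans the autosomal density, and with scores of at least 100 the ratio was 0.353 on 1 peak. In a comparison chosen after seeing the data, the X share was 5.13% of KO peaks, 1.21% of replicate 1 peaks (two-sided Fisher's exact test over peaks, adjusted p = 0.0325) and 1.76% of replicate 2 peaks (adjusted p = 0.0675). With peaks within 50 kb joined, the share was 5.17% of KO regions, on 3 regions, against 1.83% in replicate 1 (Fisher's exact test, p = 0.0944, adjusted p = 0.179) and 2.32% in replicate 2 (p = 0.179, adjusted p = 0.179), so no difference in X share was established. The 4 KO peaks on X, listed here after their values were seen, lay at 119944986 to 119945073, 120151226 to 120151410, 120155445 to 120155571 and 121328995 to 121329196, with scores of 77.9, 91.5, 73.0 and 118. The first had counterparts in replicate 1 (score 292) and replicate 2 (score 254), and the other three had none. The densest chromosome of the KO list was also chromosome 11, with 12 of the 78 peaks.

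**Figure D3:**
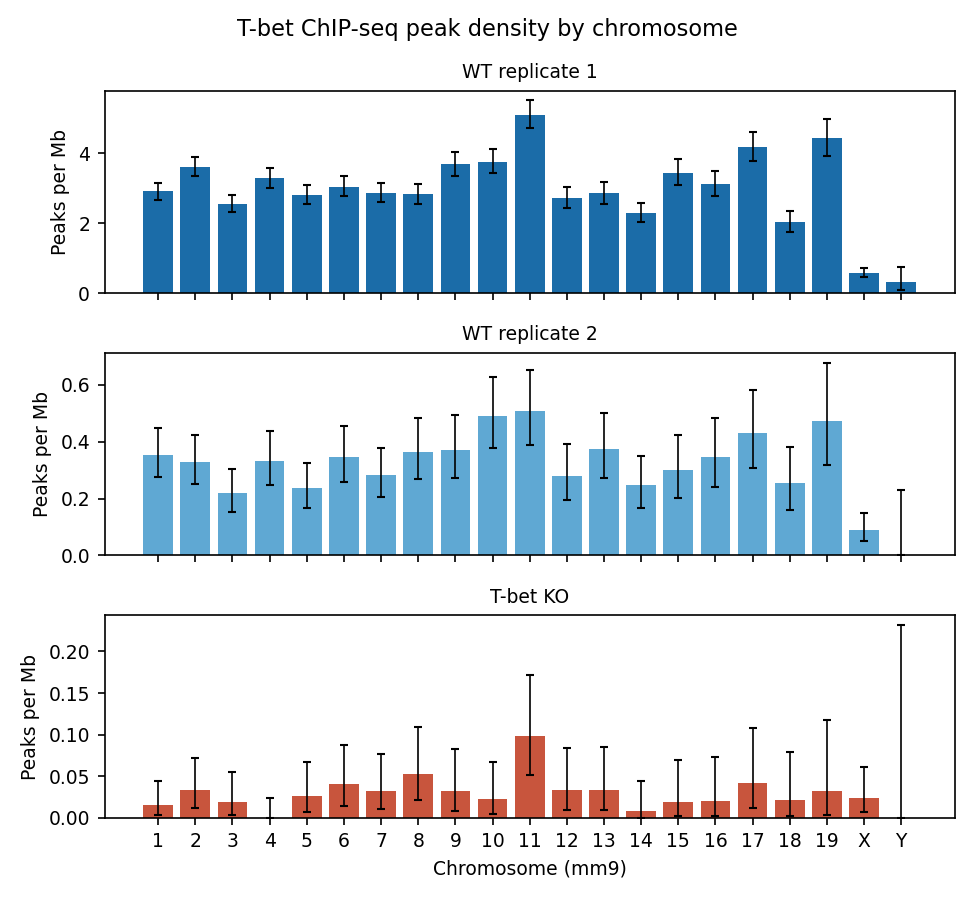
Peaks per Mb of mm9 sequence on each chromosome in WT replicate 1 (top), WT replicate 2 (middle) and the T-bet KO library (bottom), with exact 95% Poisson intervals as error bars; the y axes differ in scale. Chromosome 11 was highest in each list, at 5.10, 0.509 and 0.0985 peaks per Mb, and X was low in both WT lists, at 0.582 and 0.0900.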

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

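All 20 alternatives of the overlap and score tests, which include 1 chosen after seeing the data (KO peaks within 50 kb joined), kept their direction. Their p stayed at the smallest value each test can give, so it cannot show how stable the results are, and the ranges of the values are given instead. The share of replicate 2 peaks met by replicate 1 ranged from 46.3%, with replicate 1 cut to the length of replicate 2, to 87.7%, with scores of at least 100. The share of KO peaks met by WT peaks ranged from 15.4%, with both WT lists cut to the 78 highest peaks, to 86.1%, with scores of at least 100. It was 59.0% against replicate 2 alone and 53.8% against replicate 1 alone. Replicate 1 peaks met by replicate 2 had median scores higher by 141 (scores of at least 100) to 160 (midpoints within 250 bp). Those met by KO had median scores higher by 135 to 172 under the same alternatives. The differences in mean rank, on another scale, were 2579 and 2599. A score of at least 100 left 4582, 473 and 43 peaks in replicate 1, replicate 2 and the KO list, and 407 shared sites. The autosomal densities became 1.83, 0.189 and 0.0170 peaks per Mb, and the X densities 0.276, 0.0300 and 0.0060; the ratio of X to autosomes in the KO list became 0.353, with 1 peak on X. These falls follow from the stricter threshold, which removes peaks. The WT set without KO counterparts held 805 peaks without replicate 1 and 7952 without replicate 2, so its size is set by the shorter list. Its other alternatives stayed within 1.5 times the 726 sites. In another addition made after seeing the data, joining peaks within 50 kb lowered the ratio of the KO to the replicate 1 X share from 4.23 to 2.82 and ended the call (Fisher's exact test, adjusted p = 0.0325 before and 0.179 after). No paired analysis was possible because the inputs that share replicate numbers with the WT ChIP libraries were not analysed here and the KO group has 1 library. The planned location, gene list and T-box motif results and their alternatives were not run, for want of an mm9 annotation. Depth, which the lists do not give, limits every comparison of list lengths, and a site missing from the 2 shorter lists is not shown to be unbound.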

Other observations

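The tests of the list lengths and of site clustering were set before their results were seen; those of the KO peaks and of chromosome 11 were chosen, and their form was changed, only after the counts had been seen. Shared WT sites tended to lie near one another. Of the 726 sites, 310, or 42.7%, had another shared site within 50 kb. Random subsets of replicate 1 peaks with the same spread of scores gave a mean of 160 and a maximum of 210 such sites in 10000 draws (permutation p = 1.0e-04, the smallest the test can give). With replicate 1 peaks within 1 kb joined first, an addition made after seeing the data, 243 of 681 sites had such a neighbour, against a mean of 131 and a maximum of 182 (permutation p = 1.0e-04). The clusters with most replicate 2 peaks and no KO peak, chosen after their values were seen, were on chromosome 4 from 32337386 to 32375205 (6 replicate 1 and 5 replicate 2 peaks over 37.8 kb), on chromosome 19 from 53495480 to 53539439 (5 and 5 over 44.0 kb) and on chromosome 8 from 129357819 to 129406110 (5 and 5 over 48.3 kb). One hypothesis is that reproducible T-bet sites may gather in extended regulatory regions beyond what peak strength gives. The random subsets came from replicate 1 peaks, of which only 9.50% met a replicate 2 peak. Scatter of the peaks that did not recur could give the same result, so the test cannot decide for the hypothesis. Peaks of the KO library, which lacks T-bet, also lay near one another: joined within 50 kb, the 78 KO peaks formed 58 regions. Nearness is therefore not particular to T-bet sites, and that of KO peaks was not tested against chance. Local differences in chromatin accessibility were not tested, nor were those in copy number, which input reads could show.

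The replicate 1 list was 9.40-fold longer than the replicate 2 list. If replicate 2 were only less sensitive, most of the strongest replicate 1 peaks would recur, but 47.1% of the highest score decile did, against 1.88% of the lowest. If strong local background in replicate 1 explained the gap, most of the very highest would be missing, and 44 of the top 80 peaks, or 55.0% (43.5 to 66.2%), were. Neither prediction was met clearly, so both explanations stay open. The top 80 peaks are also a small part of the list and cannot decide what makes up the rest of the gap. The 5 highest replicate 1 peaks, chosen after seeing their values, all lacked a counterpart: chromosome 17 from 39979923 to 39985801, chromosome 2 from 98502365 to 98503171 and from 98506373 to 98507607, and chromosome 6 from 3150739 to 3151693, each with a score of 3100, and chromosome 9 from 35112780 to 35113272 with a score of 3018. The score of 3100 was the highest of the list, so the peaks that share it are not ranked among themselves. Whether it is an upper limit of the scale is not stated. These 5 peaks were not checked against repeats or regions prone to false peaks, so they are not shown to be T-bet sites. Differences between the replicates in cells, read length or peak-calling settings were not tested either.

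The KO peaks met the short replicate 2 list (46 of 78) about as often as the long replicate 1 list (42 of 78). A candidate explanation is background shared by the replicate 2 and KO libraries, as a common batch would give, and missing from replicate 1. Replicate 2 peaks met by KO would then lack a replicate 1 peak more often than the rest. They did, in 14 of 46, or 30.4% (17.7 to 45.8%), against 110 of 805, or 13.7% (two-sided Fisher's exact test over peaks, p = 0.00417). Neighbouring peaks are not independent, so the KO labels were also rotated along the replicate 2 peaks in genome order. The 851 rotations gave a mean of 6.70, and the highest other rotation also reached the observed 14 (two-sided exact rotation p = 0.0094). With replicate 2 peaks within 50 kb joined there was no difference, with 5 of 39 regions, or 12.8%, against 78 of 607, or 12.9% (two-sided Fisher's exact test, p = 1). That form was set aside after its result was seen, because a region of several peaks meets both other lists more easily. Whether this removed the difference was not tested, and the joined regions of chromosome 11 below have the same limit. The other candidate is signal independent of T-bet in every library, for which 57.1% (43.2 to 70.3%) of the KO peaks with any WT counterpart were in both WT lists. The forms of the test disagree, so the first candidate is not established. Counted by single peaks it goes with part of the pattern only, since the other 32 of the 46 peaks were also in replicate 1. That reading rests on 14 peaks and on the last of several forms of the test tried after the counts were seen. Both candidates stay open. Whether a batch is the source was not tested. The 851 highest replicate 1 peaks met 22 KO peaks, and 7 of the 20 highest replicate 2 peaks without a replicate 1 peak were KO peaks.

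Chromosome 11, which carries Tbx21, held 12 of the 78 KO peaks, against 3.60 by its length (exact binomial p = 2.4e-04, and 0.00473 after Bonferroni correction over 20 chromosomes). Neighbouring peaks account for part of the count: joined within 50 kb, they formed 6 of 58 KO regions, against 2.68 by length (exact binomial p = 0.0507). That p is not corrected for the choice among 20 chromosomes, so no excess of joined regions was established. A chromosome rich in peaks in every library remains open, since the share of joined regions was 1.49 times that of replicate 1, with 10.3% against 6.96% (Fisher's exact test, p = 0.296). Signal confined to the KO genotype is argued against as the whole cause, since 0 of the 6 regions, or 0% (0 to 45.9%), lacked a KO peak found in WT, a count that regions of several peaks pass more easily. It stays open for single peaks: 2 of the 12 had no WT counterpart, and 2 of the 6 regions (33.3%, 4.33 to 77.7%) held one. One of these peaks, from 86394688 to 86395184, lay directly beside the KO peak from 86395197 to 86396914, which had counterparts in both WT lists. The joined regions, listed after their values were seen, were at 25000073 to 25000288, 79826846 to 79845517, 86394688 to 86396914, 87240126 to 87257287, 87571670 to 87573507 and 101506914 to 101520036.

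The regions and peaks of this paragraph were chosen after their values were seen. Joined within 50 kb, KO peaks outside chromosome 11 formed 4 runs of at least 3 peaks. The run of 4 on chromosome 12 from 55811211 to 55839694 had a WT counterpart for each peak. The run of 3 on chromosome 2 from 147012076 to 147012871 had none, with a highest score of 207. The run of 4 on chromosome 8 from 19723363 to 19763612 had none, and the run of 3 there from 19906828 to 19957135 had 1. Another 4 regions, on chromosomes 5, 6, 19 and X, held 2 peaks each. Replicate 1 had 5 peaks on Y, of which the highest, from 2652204 to 2652349, scored 356, and 1 on the mitochondrial genome, from 1744 to 4728, with a score of 130; replicate 2 and the KO list had none on either.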
